A study of Mus musculus with 37 samples.

How the data were processed

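Single granulocyte-monocyte progenitors (GMP) from mouse bone marrow carrying an Irf8-GFP reporter were profiled by single-cell RNA sequencing. The labels give 37 cells in 1 group, each cell a sample of its own. Per the labels' protocols, marrow was enriched for CD117, sorted by flow cytometry, and captured on a Fluidigm C1 instrument. Complementary DNA was made with a SMARTer kit and libraries with a Nextera XT kit. These kits do not mark strand, so transcripts of a gene and of an overlapping antisense gene cannot be told apart. Their products carry no molecular identifiers. The labels differ on the gate: the sample descriptions and the cell type label give cells without CD115 and with dim GFP, while the protocol gives intermediate levels of both. The strain is written C57BL/7 in the labels. Titles mark 4 of the 37 cells as of poor quality (cells 12, 29, 33 and 37).

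The deposited table holds 23955 gene symbols by 37 columns, and all 37 columns were used. Column numbers were matched to the cell numbers in the titles. The submitters' processing notes list Bowtie2, RSEM and the mouse build mm9, without versions or roles, and the annotation is not given in the sources used here. The table has no note of its unit, so units were read from the values. In 33 columns the authors deposited log2 values, log2(TPM + 1), where TPM is the transcript abundance scaled to a fixed total. Once the log is undone, each column sums to 1000000 within rounding and its values are multiples of 0.01. In the 4 columns of cells marked poor quality, the authors deposited TPM on the linear scale, with the same sum. All columns were brought to linear TPM before any step. TPM keeps no read totals, so depth per cell is unknown and no value carries a depth-based error. Of the symbols, 22660 are also in the reference gene table used here, which belongs to another build than the authors' own, so no coordinates are given.

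The labels name no animal, culture or batch, so the 33 cells not marked poor quality were treated as 1 sample. No p-value or standard error was made from cells, and every statement describes these cells only. A gene was called detected in a cell at 1 TPM or more. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. A gene listed at 0 TPM may be unexpressed, missed in amplification or lost in the estimate of transcript levels: Tbp, a general transcription factor, was at 0 in 9 of the 33 cells. Thus "not detected" never means absent here. Levels are given as log2(TPM + 1) with the SD over cells, or as TPM.

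Before the data were examined, 19 gene lists were fixed. They cover primary granule with neutrophil progenitor, secondary granule with late neutrophil, monocyte, dendritic cell, and stem and multipotent progenitor genes. Other lineages covered are erythroid, megakaryocyte, basophil with eosinophil and mast cell, B cell, T and NK cell, and stroma with endothelium. The first list is called primary granule for short, although it is not limited to granule genes. Further lists hold S phase, G2 and M phase, immediate early with heat shock, interferon response, sort gate, myeloid fate regulator, housekeeping and sex-linked genes. The listed genes Ly6g, Ighm and Trbc1 were not analysed here. Named genes follow a rule fixed at the same time: Irf8, Gfi1 and the sort gate genes, and up to 4 members per list with the highest mean. For other lineages, a member had to be detected in at least 20% of cells. The rule adds the 10 genes with the highest mean apart from ribosomal protein and mitochondrial genes, and the 10 most positive and 10 most negative correlations with Irf8 and with Gfi1. The last part is the 10 genes with the largest excess variance. Other genes named are listed members or genes chosen after their values were seen, as stated.

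Co-detection of a pair of genes was set against the number expected from their separate shares. Its percentile was taken among 10000 random gene pairs matched on detection and mean level. Mixed detection counted cells with at least 3 detected genes of each of a pair of lists. A list score was the mean over members detected in at least 10% of cells of log2(TPM + 1) scaled to unit SD. For 25 relations fixed in advance, Pearson's r and Spearman's rho were computed across cells. Each rho was placed among 10000 random genes or lists of the same size, each member replaced by 1 of the 100 genes closest in mean level and detection. A list set against a single gene was drawn with that gene held, and otherwise both sides were drawn. A relation was called when rho lay outside the central 95% of the random values. At the nominal rate, 1.25 of 25 relations would do so. Random members were drawn separately, so random lists lack the relations that members of a real list may have.

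For each of 6669 genes detected in at least 30% of cells, rho with Irf8 and with Gfi1 was computed. The number of genes at or beyond 0.5 was compared with the same number for 100 matched random genes. On simulated data for the Irf8 relations, each gene was shuffled over cells on its own, and 200 genes were then tied strongly to Irf8. Over those 6669 genes, 99.5% of the 200 were recovered, and 0.396% of unrelated genes passed. The recovery holds for such strong ties only. Shuffling also removed trends that genes share across the real cells, so neither rate carries over to them. Principal components were taken over the 500 genes whose log2 variance lay farthest above a polynomial curve fitted on their mean. The curve runs low at the highest means and so favours some abundant genes, 11 of them with a mean of 12 or more on the log2 scale among the 500. They were compared with 100 data sets in which each gene was shuffled over cells. No doublet caller was run on 33 cells. Instead, cells holding both Xist and Y-linked transcripts were counted.

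Alternatives covered detection thresholds, pseudocounts of 0.1 and 10, inclusion of the marked cells, rescaling, list scoring, Pearson's r, and partial rho given genes detected. They also covered filters, the number of genes for the components, and leaving out each cell in turn with 2000 random draws each. Subsets of cells with Xist only, cells with Y-linked transcripts only, cells other than cell 1, and cells other than cells 1 and 14 were added after the data were seen, as was an expected variance from the 100 genes closest in mean. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.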

Results

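The transcriptomes of 37 single Irf8-GFP GMP from mouse bone marrow were measured. GMP are progenitors that give rise to neutrophils and monocytes. Irf8 is a transcription factor of monocyte and dendritic cell development, and the reporter marks cells that express it. Gfi1 is a transcriptional repressor needed for neutrophil development. The data bear on whether single progenitors hold transcripts of both fates at once. There was 1 group and no second condition, so the comparisons lie between genes within these cells. All values below are from the 33 cells not marked poor quality unless stated, which count as 1 sample without replicates.

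Between 1713 and 6165 genes were detected per cell, with a median of 5131. Cell 1 had the fewest, and the next lowest had 3401. Cell 14 stood apart in another way, with ribosomal RNA of Rn45s at 22316 TPM, inside the 21719 to 55364 of the marked cells. Its share of TPM in ribosomal protein genes, 31.0%, was close to the 29.6% of cell 27 (median 17.9%). The 20 highest genes of a cell took 12.3% to 20.9% of its TPM, with a median of 14.3%. In the 4 cells marked poor quality, 1490 to 2638 genes were detected and the 20 highest took 32.4% to 81.9%. Read depth is unknown, so differences in gene number cannot be set against it. All 15 housekeeping genes on the fixed list were detected in over 50% of cells. Eef1a1, a translation elongation factor, and Actb, cytoskeletal actin, had means of 13.51 (SD 0.50) and 13.15 (SD 0.42) on the log2 scale. Ppia, a peptidyl-prolyl isomerase, and Ubb, a ubiquitin gene, were close behind at 12.85 and 12.67.

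**Figure D1:**
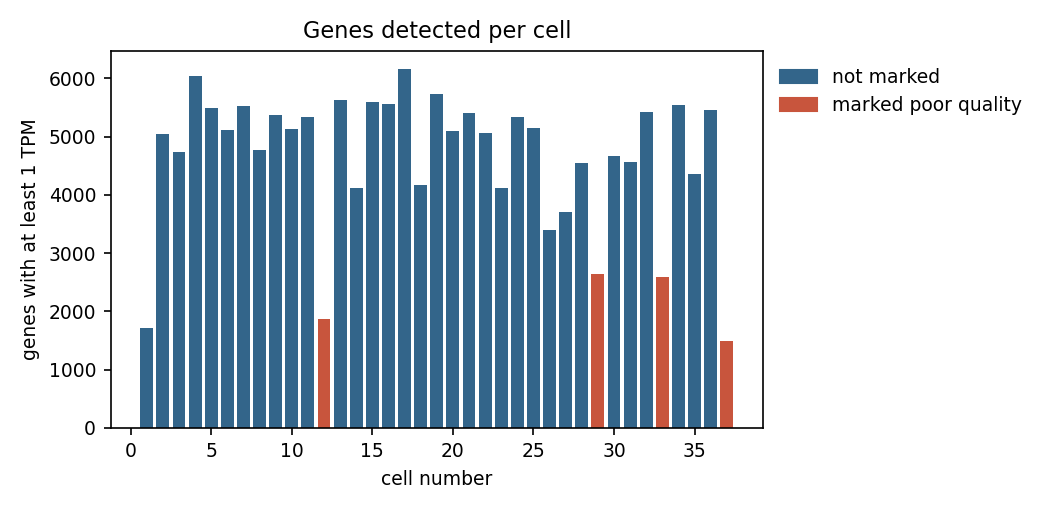
Bars give the number of genes at 1 TPM or more in each of the 37 cells, by cell number, with the 4 cells marked poor quality in red. The marked cells hold 1490 to 2638 genes, and cell 1 is the only unmarked cell in that range, with 1713.

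Genes of the primary (azurophil) granules of neutrophils were the dominant lineage transcripts in these progenitors. Mpo, myeloperoxidase, had the highest mean of all genes in the table on the log2 scale, with a median of 13749 TPM and a range of 3185 to 29469. The serine proteases Elane, Prtn3 and Ctsg were also detected in 33 of 33 cells, at medians of 9474, 2464 and 2578 TPM. Of the 15 genes on the primary granule and neutrophil progenitor list, 12 were detected in at least 50% of cells, and a cell held 7 to 14 of them. Of Mpo and the 3 proteases, Elane had the widest relative span, from 4.2 to 24482 TPM. Secondary granule and late neutrophil genes were mostly not detected: 8 of 14 were detected in no cell, among them Ltf, lactoferrin, and Camp, cathelicidin. The alarmin subunit S100a8 was detected in 13 cells (39.4%, interval 22.9% to 57.9%). The chemokine receptor Cxcr2 was detected in all 33 at a median of 45.6 TPM.

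Monocyte genes were present in the same cells at lower levels. Of 20 measured, 8 were detected in at least 50% of cells and 3 in none, and a cell held 5 to 12. Ly6c2, a surface marker of classical monocytes, was detected in 29 cells at a median of 1696 TPM over all cells. Its near-identical copy Ly6c1 makes this value uncertain. Slpi, a protease inhibitor, was detected in 29 cells, the chemokine Ccl9 in 31, and Ms4a6c in 28. The receptor gene Csf1r, which encodes CD115, was detected in 16 cells (48.5%, interval 30.8% to 66.5%). Mafb, Fcgr1 and Lgals3, expressed in mature monocytes and macrophages, were detected in none. At least 3 genes of the primary granule list and 3 monocyte genes were detected together in 33 of 33 cells (100%, interval 89.4% to 100%). Each cell held at least 7 of the first and 5 of the second, so this count is saturated and tells no cells apart. The 4 cells marked poor quality also passed this count. Requiring at least 3 dendritic cell genes in place of the monocyte genes left 9 cells, and at least 3 B cell genes left 0 of 33 (upper limit 10.6%). S phase genes, and G2 and M phase genes, in their place also gave 33 cells each.

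Progenitor genes accompanied both programmes. Of 18 stem and multipotent progenitor genes, 5 were detected in at least 50% of cells, and 31 cells (93.9%, interval 79.8% to 99.3%) held at least 3 beside primary granule genes. Gpr56, an adhesion receptor, was detected in 27 cells, and Cd27, a receptor of the tumour necrosis factor family, in 26. Egr1, an immediate early transcription factor, was detected in 21 cells, and Ly6a in 25. Ly6a encodes Sca-1, which the sort excluded at the protein level. Its median was 10.1 TPM, and it belongs to a family of similar genes whose reads can be shared. Mpl and Mycn were detected in no cell.

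Genes of lineages outside the gate were sparse, with a few exceptions. The median member of the erythroid, megakaryocyte, basophil, B cell, and stroma lists was detected in 0% of cells, and that of the T and NK list in 3.03%. Among erythroid genes, 12 of 18 were detected in no cell, Gata1 included, while Tfrc, the transferrin receptor, was detected in 22 cells and Car2, a carbonic anhydrase, in 11. Of 13 megakaryocyte genes, 8 were in no cell. Those detected were led by Fli1, an Ets transcription factor, in 31 cells, and Cd9, a tetraspanin, in 23. Hdc, histidine decarboxylase, was detected in 26 cells, Mcpt8, a basophil protease, in 19, and Cpa3, a mast cell carboxypeptidase, in 15. The other members of that list were in at most 6 cells, and 13 cells (39.4%) held at least 3 of its 18 genes. Of 14 B cell genes, Cd79b, a subunit of the B cell receptor, was detected in 17 cells and no other in more than 2. The T cell kinase Lck was detected in 7 cells. Of 17 dendritic cell genes, Tcf4, a transcription factor, was detected in 26 cells, Bst2 in 14, H2-Ab1 in 10 and no other in more than 6. Of 12 stroma and endothelium genes, Lepr was detected in 29 cells at a median of 2.3 TPM and Pecam1 in 19.

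**Figure D2:**
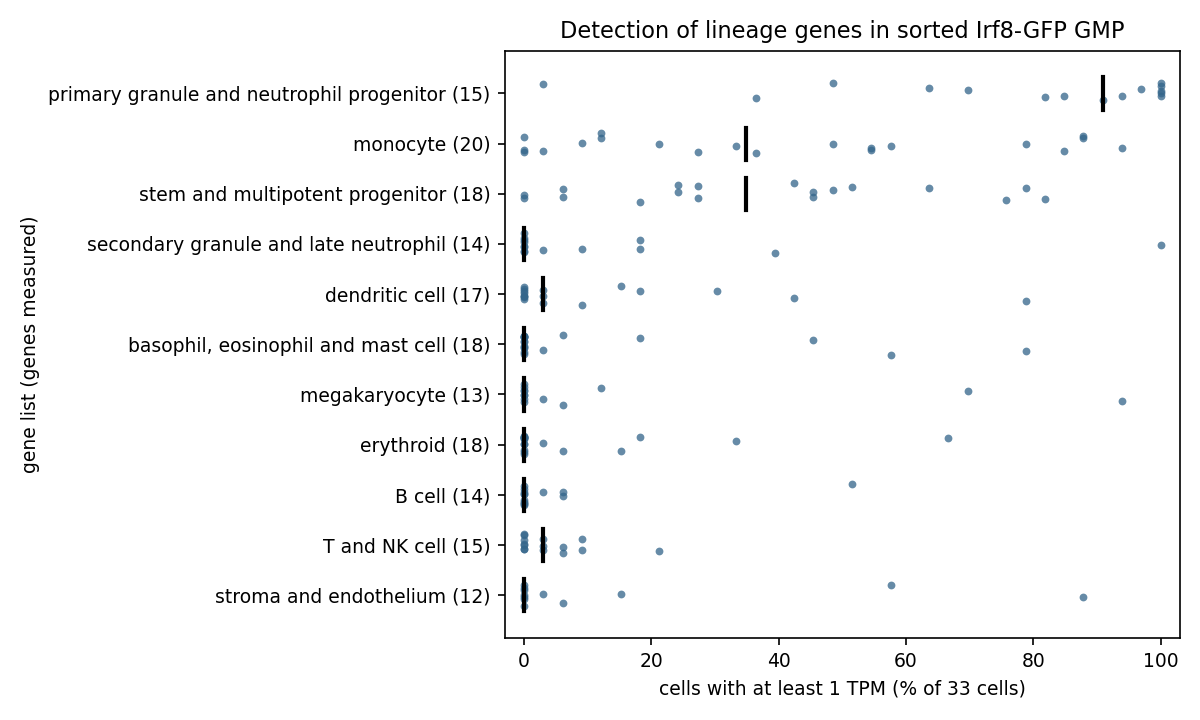
Each point is 1 gene of a fixed list, placed by the percentage of the 33 cells with at least 1 TPM, and the black bar is the list's median, with points spread vertically for visibility. The primary granule list has a median of 90.9%, the monocyte and the stem and multipotent progenitor lists 34.8% each, and most other lineage lists 0%.

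Transcripts matched the sort gate for some markers and not for others. Kit, which encodes CD117, and Cd34 were detected in 32 cells each, at medians of 56.4 and 270 TPM. Fcgr3 and Fcgr2b, the genes of CD16 and CD32, were detected in 26 and 24 cells, Ptprc, which encodes CD45, in 26, and Ly6c1 in 23. Of genes whose products the sort excluded or stained against, Cd3e, Cd19 and Ccr3 were detected in no cell, Cd4 in 1, Cd8a in 2, Itgam in 4, and Flt3 and Siglec5 in 6 each. Against this, Ly6a (Sca-1, excluded by the sort) was detected in 25 cells. Csf1r was detected in 16, and the labels differ on its product CD115, negative in the sample descriptions and intermediate in the protocol.

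Most cells carried transcripts of the cell cycle. Of 25 S phase genes, 23 were detected in at least 50% of cells. They included the replication clamp Pcna (33 cells, median 549 TPM), Rfc2, Rrm2 and the helicase subunit Mcm7. Of 27 genes of G2 and M phase, 20 were detected that often. Hmgb2 was detected in 33 cells, Cks2 in 32, Top2a, a topoisomerase, in 30 and Cdk1 in 28. Immediate early and heat shock genes were also common, 12 of 16 in at least 50% of cells, with Hspa8 at a median of 6527 TPM, Fos at 350 and Jun at 28.4. No interferon response gene of 12 reached 50% of cells. The most frequent were Oas1a in 15 cells and Stat1 in 12.

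Irf8 was detected in 25 of 33 cells (75.8%) and Gfi1 in 16 (48.5%). Both were detected in 11 cells (33.3%, interval 18.0% to 51.8%), Irf8 without Gfi1 in 14, Gfi1 without Irf8 in 5, and neither in 3. Independent detection would give 12.1 cells with both, and the shortfall of 1.12 cells lay at the 10.1 percentile of matched random gene pairs. Levels across cells were not related beyond matched random genes, with Pearson's r of -0.17 and Spearman's rho of -0.09 (random rho -0.30 to 0.38). Without the 2 cells farthest from the median Irf8 level, r was -0.27 and rho -0.21, for which no random range was made. Where detected, the median was 37.7 TPM for Irf8 and 15.8 TPM for Gfi1, and the highest values were 304 and 389 TPM. At a threshold of 10 TPM, the share of cells with both was 15.2%. The sort selected on the Irf8 reporter, with dim or intermediate GFP by the labels. These shares and the relation of Irf8 with Gfi1 thus describe cells of that gate, and not GMP outside it.

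**Figure D3:**
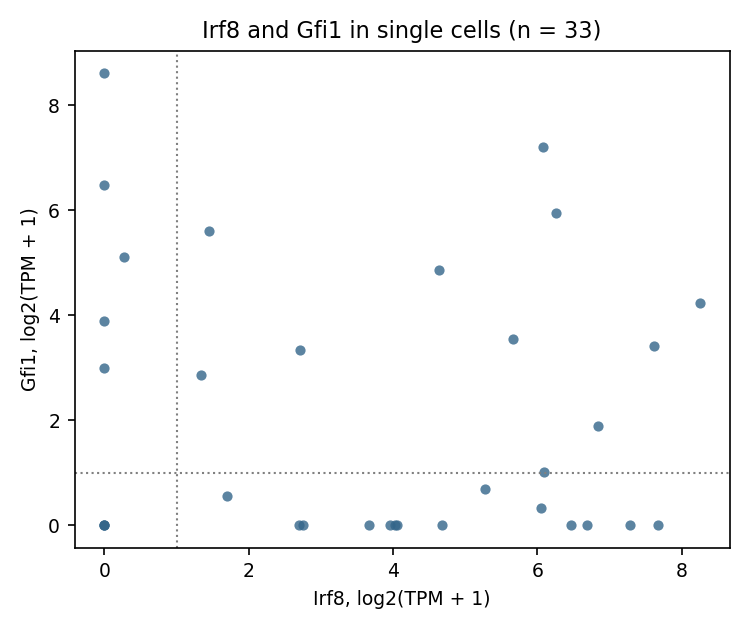
Each point is 1 of 33 cells, with Irf8 on the horizontal and Gfi1 on the vertical axis as log2(TPM + 1), and dotted lines at 1 TPM. Both transcripts pass 1 TPM in 11 cells. Over all 33 cells rho is -0.09, and without the 2 cells farthest from the median Irf8 level it is -0.21.

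Detection of regulators of myeloid fate varied from gene to gene. Of 40 on the list, Irf8 and Gfi1 included, 18 were detected in at least 50% of cells and 5 in none, with a median of 45.5% of cells. The progenitor factors Myb, Myc and Lmo2 were detected in 33, 32 and 32 cells, and Fos in 25. Of further list members chosen here for their known roles, Cebpa was detected in 19 cells, Spi1, which encodes PU.1, in 26, Zeb2 in 26, Klf4 in 12 and Cebpe in 12. The pairs given next had the lowest and the highest percentile of all pairs examined for co-detection, and none of those pairs lay outside its range. Klf4 and Irf8 were detected together in 7 cells against 9.09 expected, and Irf8 and Zeb2 in 22 against 19.7. The first lay exactly on the lower bound of its matched random range, at the 2.1 percentile counting ties as shared, and the second inside its range.

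Across the 33 cells, the monocyte score ran weakly against mitotic and stem genes, while matched random lists mostly rose together. The monocyte score fell with the G2 and M phase score (rho -0.24, r -0.20), where matched random lists had a median rho of 0.41 and a range of 0.12 to 0.65. With the stem score, rho was -0.26 and r -0.25, against a random range of -0.01 to 0.59. No such difference was seen between monocyte and S phase scores (rho 0.32, random 0.10 to 0.64). Without the 2 cells farthest from the median monocyte score, r was -0.24 with G2 and M phase and -0.16 with stem. In the 13 cells with Xist only, the relation with stem was 0.04 and inside its range.

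Primary granule and monocyte scores rose together, with rho of 0.54 (r 0.51), just above the random range of -0.17 to 0.51. Primary and secondary granule scores also rose together (rho 0.48, r 0.42, random -0.27 to 0.43). The secondary granule score held only 4 genes: Lcn2, S100a8, Padi4 and Cxcr2, detected in 6, 13, 6 and 33 cells. Ltf and Camp were detected in no cell and did not enter it. The relation thus does not speak for the secondary granule list as a whole. Without the 2 cells farthest from the median primary granule score, r was 0.50 with the monocyte and 0.45 with the secondary granule score. The first relation was inside its range in 8 of 14 alternatives, including division by the upper quartile (0.53) and the 17 cells with Y-linked transcripts only (0.18). The second was inside in 5 of 14, including r (0.42) and the cells with Xist only (0.14).

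Irf8 rose with the monocyte score (rho 0.38, r 0.40, random -0.19 to 0.37), and Gfi1 fell with the stem score (rho -0.25, r -0.23, random -0.24 to 0.33). Both lay at the edge of their ranges. Without the 2 cells farthest from the median, r was 0.28 and -0.10, and leaving out single cells ended the first call in 18 of 33 fits (rho 0.25 without cell 8) and the second in 16 (rho -0.19 without cell 26). Neither regulator had a relation with the primary granule score outside the random range (rho -0.01 for Irf8 and 0.04 for Gfi1). In all, 6 of the 25 relations lay outside their ranges, against a nominal 1.25. The number was 3 without cell 27, 3 without the 25% of cells with the fewest genes, and 2 in the cells with Xist only. The nominal number takes members of a list to be no more related to each other than matched random genes. The relations also share scores, so the 6 are not a tested excess.

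**Figure D4:**
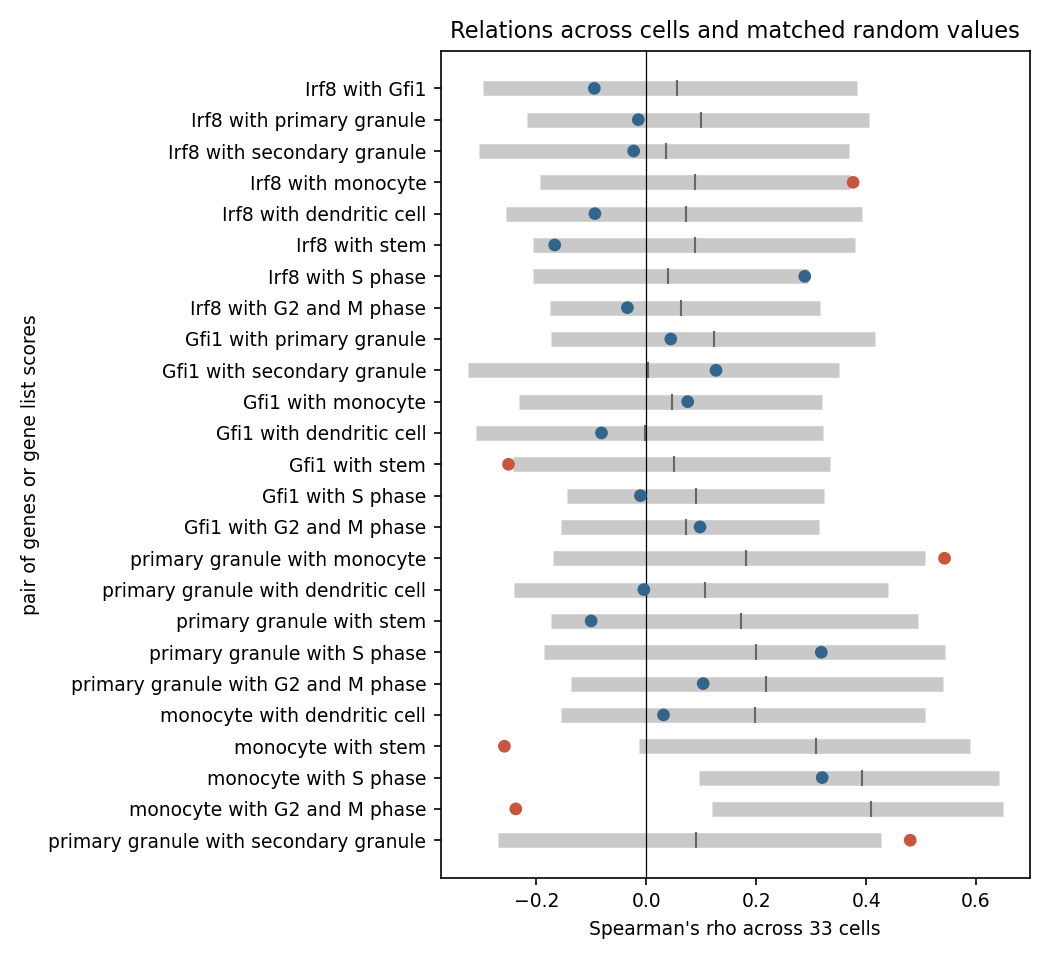
Points give Spearman's rho across 33 cells for each of the 25 pairs, red where outside the central 95% of matched random values (grey bars, with a tick at the median). Monocyte with G2 and M phase, at -0.24, lies farthest below its range, which starts at 0.12.

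In these 33 cells, the number of genes that followed either regulator lay within the range of matched random genes. Of 6669 genes, 21 had a rho with Irf8 at or above 0.5 and 6 at or below -0.5, where random genes had medians of 25.5 and 4. For Gfi1 the numbers were 11 and 10, against 22 and 5. The genes most positive with Irf8 were Anxa2, an annexin, at 0.58, Ung, a uracil glycosylase, at 0.58, Ms4a6b at 0.58 and Milr1 at 0.57, followed by Ivd, Tnfaip8, Rgs10, Impdh2, Sufu and Upf2. The most negative were Eif4a1, a translation initiation helicase, at -0.56, Ddx26b at -0.54 and Kmt2d, a histone methyltransferase, at -0.52. With Gfi1, Zdhhc21 (0.58), Shmt2 (0.57) and Sec61b (0.54) were most positive, and Mettl2 (-0.64), Dcaf6 (-0.59) and Bloc1s3 (-0.58) most negative. Counts changed by over 1.5 times without cell 1, which left 12 positive and 15 negative genes for Irf8, and without cell 26, which left 27 positive and 5 negative for Gfi1.

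The first principal components were carried by 2 cells. Of the components, 3 exceeded shuffled data, with 20.3%, 7.50% and 5.40% of the variance against at most 5.05%. On the first, cell 1 scored -0.87 and cell 14 -0.33, with all others between -0.12 and 0.09. On the second, cell 14 scored -0.85 and cell 1 0.42, with all others between -0.11 and 0.10. By rank, the first had a rho of 0.86 with genes detected, 0.62 with the G2 and M phase score, and 0.16 and 0.14 with Irf8 and Gfi1. Without cells 1 and 14, a split chosen after the data were seen, 4 components exceeded shuffled data, the first with 10.3% of the variance. It had a rho of 0.79 with genes detected, 0.69 with G2 and M phase, 0.23 with primary granule and -0.17 with monocyte genes, and 2 of the 31 cells scored highest, at 0.52 and 0.49 in size. The second, with 7.65%, had a rho of -0.74 with primary granule, -0.59 with monocyte and 0.48 with stem genes, with the highest cells at 0.69 and 0.66 in size. These components too were thus carried in large part by few cells. The genes farthest above the fitted curve of variance on mean were Elane, Mpo, Ly6c2, Rps27, Rps27rt, Slc25a5, Eef1a1, Plac8, Ms4a3 and Gstm1. That curve ran too low at the highest means: the 3 genes with a mean of 13 or more were all among the 500 used, with a median excess of 2.73 on the log2 scale of variance. Against the genes closest in mean, a check added after the data were seen, Eef1a1 had no excess (-0.10), and Mpo and Plac8 fell to ranks 134 and 42. Their places in this list reflect their level at least in part. Elane stayed at rank 1, and the other 6 stayed within rank 11. The 500 genes of that check shared 355 with the main ones, again 3 components exceeded shuffled data, and cells 1 and 14 again scored farthest on the first and second. Rps27 and Rps27rt are near-identical copies that can share reads, so their values are uncertain. The genes with the highest means were Mpo, Eef1a1, Actb, Ppia, Ubb, Plac8, Hspa8, Elane, Gpx1 and Ptma.

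Of the 33 cells, 13 held Xist without a Y-linked transcript, 17 held Y-linked transcripts without Xist, 3 held neither and 0 held both. Of the 4 marked cells, 1 held both. The cells thus came from at least 1 female and 1 male mouse, which the labels do not state. Relations within each of these subsets are given with the alternatives.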

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

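The genes in this part, and the comparison of marked with unmarked cells, were chosen after the values were seen. No cause was tested.

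In the 4 cells marked poor quality, 3 transcripts were far higher than in any other cell. Klk14, a kallikrein-related peptidase gene, was at 27131 TPM or more in each of the 4, against at most 1781 in the 33 unmarked cells. Pigr, the polymeric immunoglobulin receptor gene, was at 6718 TPM or more, against at most 315. Gm20594 was at 24009 TPM or more, against at most 3043. Irf8 and Gfi1 were at 0 in all 4, and Mpo was still at 1052 TPM or more.

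Among these 4 cells, 1 cell lay far from the other 3 in 4 of 9 measures tested. Chance alone sets 1 value apart in about 1 in 20 such tests, and these measures share transcripts, so they are not independent. In cell 12, the 20 highest genes took 81.9% of TPM, Klk14 reached 368249 TPM and Pigr 85848 TPM. In cell 29, Mpo reached 11996 TPM, within the range of the unmarked cells.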

How the results depend on the processing

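The subsets by Xist or Y-linked transcripts, the omissions of cell 1 and of cells 1 and 14 together, and the expected variance from the genes closest in mean were chosen after the data were seen, and the other alternatives were planned. The cause of a change was not tested unless the setting itself gives it, as a higher threshold or fewer cells do. Depth is unknown, so its effect could not be examined directly. Across 14 alternatives, monocyte with G2 and M phase stayed outside its random range in 14 (rho or r -0.54 to -0.08), and in all 33 fits without 1 cell. In the main analysis that range was 0.12 to 0.65, wholly above 0, so a relation near 0 also counts as outside. The calls thus show the lack of a joint rise seen in random lists, and not a strong opposition. Monocyte with stem stayed outside in 11 of 14 and in 33 of 33 fits, and in the cells with Xist only it turned to 0.044. Irf8 with Gfi1 stayed inside in all 14. Gfi1 with stem stayed outside in 5 of 14 and 17 of 33 fits.

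At least 10 TPM as the threshold gave a median of 4015 genes, Irf8 in 57.6% of cells, Gfi1 in 30.3% and both in 15.2%. Mixed granule and monocyte detection is saturated: each cell held at least 7 primary granule and 5 monocyte genes, so its alternatives say nothing of stability. At least 10 TPM gave 97.0%.

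Primary granule with monocyte was inside its range with the marked cells included (0.67), division by the upper quartile (0.53), all list members (0.35), unscaled means (0.50) and Pearson's r (0.51). The same held without the 25% of cells with the fewest genes (0.34), with Xist only (0.44) and with Y-linked transcripts only (0.18). Leaving out single cells gave 0.48 to 0.61, inside the range without cell 9, 10, 11, 20, 25, 27 or 36. Irf8 with monocyte was inside with a pseudocount of 10 (0.37), rescaling without the 20 highest genes (0.37), unscaled means (0.35), partial rho given genes detected (0.38) and Xist only (0.083). In the other 9 of 14 alternatives it was outside. Over the 14 its value ran from 0.083 (Xist only) to 0.75, so its size was not stable over settings and subsets of cells. Leaving out single cells gave 0.25 (cell 8) to 0.47. The call ended without cell 2, 5, 6, 8, 9, 11, 13, 16, 17, 18, 19, 20, 21, 24, 27, 30, 35 or 36. Of relations inside their ranges in the main analysis, primary granule with stem was outside in 6 of 14 alternatives, as often as primary granule with monocyte, Irf8 with S phase in 4 and primary granule with G2 and M phase in 3. Gfi1 with primary granule was outside in 1 (-0.40, Y-linked transcripts only), and Gfi1 with dendritic cell, Irf8 with G2 and M phase, Irf8 with stem and monocyte with S phase in 1 each. The number of relations outside was 3 without the 25% of cells with the fewest genes and 2 with Xist only. It was 3 to 7 over the omissions of single cells, with 3 without cell 27.

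Numbers of genes beyond the rho threshold were unstable. With the marked cells included, 77 were positive and 0 negative with Irf8, and 32 positive with Gfi1. The 7 negative with Gfi1 then lay above the random range of 0 to 6.53, unlike the 10 in the 33 cells (0 to 15.6). Division by the upper quartile left 2 negative with Irf8, 6 positive with Gfi1 and 6 negative with Gfi1. Genes in at least 60% of cells gave 13 positive with Irf8 and 6 negative with Gfi1, and genes in at least 1 cell gave 17 positive with Gfi1. At a rho of 0.6, no gene was left with Irf8 (0 positive, 0 negative), and 0 positive and 1 negative with Gfi1. Without cell 1, there were 12 positive and 15 negative with Irf8 and 6 positive with Gfi1, the last below the random range of 7 to 56.1. Without cell 27, the 6 positive with Gfi1 also lay below their range of 7.95 to 72.2. Omitting single cells gave 12 to 30 positive and 4 to 15 negative with Irf8, and 6 to 27 positive and 5 to 15 negative with Gfi1. Changes over 1.5 times came without cell 1, 2, 3, 20, 26, 27 or 28. Components above shuffled data numbered 1 with the marked cells included and 2 to 4 over the omissions of single cells. They numbered 3, as in the main analysis, with the expected variance from the genes closest in mean.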

Other observations

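The tests below of paired cells, of stray RNA, of S phase, of cells left out at random and of the size of rho without 1 cell were chosen after the results they concern were seen.

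Some list members outside the named set had a rho with Irf8 or Gfi1 short of the cut of 0.5, chosen here after their values were seen. Cebpa, a transcription factor of granulocyte development, had a rho of -0.47 with Irf8 and 0.14 with Gfi1. Cebpb had -0.46 with Gfi1 and 0.32 with Irf8, and the monocyte receptor Cd14 had -0.46 with Gfi1 and -0.02 with Irf8. None reached 0.5, and these were picked from all list members with no correction for that choice. Per3, a circadian regulator, was detected in 22 cells and Nfe2, an erythroid and megakaryocyte factor, in 26, while Gata1 was detected in none.

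Cxcr2 stood apart from other late neutrophil genes. It was detected in all 33 cells, at 7 to 246 TPM (SD 1.18 on the log2 scale), and in all 4 marked cells. By contrast, Ltf, Camp and Mmp8 were detected in none of the 33.

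Primary granule and monocyte scores rose together across the cells, outside the random range in 6 of 14 alternatives, which a shared technical trend, cell cycle stage or differentiation could produce. These were tested from the gene lists, since the labels give 1 group and no contrast. A difference between the female and male mice was not tested and stays open. Within the cells with Xist only rho was 0.44, and within those with Y-linked transcripts only 0.18, each inside its range. The tables argue against the number of genes detected per cell as the whole cause: given it, partial rho was 0.58, above the random range of -0.29 to 0.40. Without the 25% of cells with the fewest genes, however, rho fell to 0.34, inside its range of -0.39 to 0.43, and the partial rho of the 24 cells left was 0.38, inside -0.43 to 0.40. Leaving out 9 cells at random gave a rho that low in 130 of 1000 draws (0.23 to 0.68 in 95%), so the fall can come from fewer cells and does not by itself support the explanation, but the pattern is not firm. The G2 and M phase score had a rho of 0.10 with primary granule and -0.24 with monocyte, opposite in sign. As measured it thus does not account for a joint rise. The partial rho given it, 0.59 (range -0.27 to 0.43), adds nothing, since holding that score fixed could not lower rho. Given the stem score, partial rho was 0.54 (range -0.22 to 0.47), so the stem score as measured does not account for the relation. That score had a rho of only -0.10 with primary granule and -0.26 with monocyte, so holding it fixed could change little. The median gene of its list was detected in 34.8% of cells. Loss of stem cell transcripts with differentiation therefore stays open. No 1 cell carried the size of rho, which was 0.48 at its lowest without 1 cell against a random median of 0.18, although 7 of 33 omissions ended the call because its bound lies close. S phase stays open: its own relation with either score lay inside its random range (rho 0.32 with each, -0.19 to 0.54 for primary granule and 0.10 to 0.64 for monocyte), and given it rho moved from 0.54 to 0.49, just inside a range of -0.18 to 0.50.

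Irf8 and Gfi1 transcripts were detected in the same 11 cells, which 2 cells in 1 chamber or stray RNA could give. Of these 11, 0 held Xist with a Y-linked transcript, where 11 random pairs of these cells would give 5 (2 to 8 in 95% of draws). That argues against 2 cells in 1 chamber for all 11, and only if cells of both sexes were loaded together. It could not exclude a few such chambers among the 11. The labels do not say whether the sexes were loaded together, and 1 of 4 marked cells with both kinds of transcript is too few to settle it. Stray RNA at low level also stays open: 5 of the 11 cells held both at 10 TPM or more and 6 did not. Of 29 listed B, T and NK cell genes, the median member reached 10 TPM in 0 of the 33 cells and the most frequent, Cd79b, in 15. These speak of stray RNA from lymphocytes only, and that from other progenitors was not measured. Joint expression in single progenitors is thus a hypothesis.

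Transcripts listed for other lineages were detected in most cells for 10 genes: Cd79b, Cd9, Cxcr2, Fli1, Hdc, Lepr, Mcpt8, Pecam1, Tcf4 and Tfrc. Sequence shared with another detected gene could give this, and 0 of the 10 shared over 20% of their 50-base words with transcripts of a gene of higher mean level. The largest such share was 1.09%, for Cxcr2 with Pbld1. Transcripts of the reference build were searched, not those of the authors' build, and intronic or repeat sequence was not. Expression of these genes in progenitors, or RNA of other cells, stays open and was not tested.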
